A study of Schizosaccharomyces pombe with 11 samples.

How the data were processed

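The series holds 11 2-colour Agilent 60-mer tiling arrays of Schizosaccharomyces pombe, with BrdU-immunoprecipitated DNA in Cy5 and whole-cell extract DNA in Cy3, both amplified by random-primed PCR per the labels. Groups come from the labels. Series 1 has wt, taz1del and clr4del, each at 100, 120 and 140 min (replicates 1, 2 and 3 in this order), and series 2 has wt and telr delta Is3 at 80 min. The labels give no second array of a genotype at a time, so p-values measure the spread between time points, not between cultures. The labels do not say what the name telr delta Is3 stands for. Per the file headers, the authors' scanner files hold intensity values from Feature Extraction (11.5.1.1 for series 1 and 10.7.3.1 for series 2), background subtracted, spatially detrended and linearly dye normalized, with no lowess term and no normalization between arrays. The deposited value table holds log2 ratios of the processed red over green signals and equals those computed here from the scanner files.

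The log2 ratio of processed Cy5 over Cy3 signal was taken for 41551 probes per array and centred on each array's median. The 41251 chromosomal probes, about 300 bp apart, were averaged in non-overlapping windows of 2000 bp with at least 3 probes, which gave 6207 windows in series 1 and 6223 in series 2. Another 110 probes named mat, 61 named mito and 129 named pNSU were kept apart, and no spot was saturated. Between 15 and 40 probes per array were not well above background in the input channel.

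The genome build behind the array coordinates is not given in the sources used here. A reference genome and annotation served only to find genes and hexamer sites, after each chromosome arm was registered on it by the shift at which input signal best followed GC content, with offsets between -4500 and 1660 bp. At the best offset r was 0.221 to 0.253, and no more than 0.0544 at offsets far from it. Every printed position is an array coordinate.

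Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 7.11 prior degrees of freedom), with genotype and time as factors over the 9 arrays of series 1 and a Benjamini-Hochberg adjusted p under 0.05 as the threshold over all windows. Called windows of 1 direction at most 2 windows apart were merged into domains. Before the data were examined, it was fixed that the 12 domains with the largest mean in each direction and the same sign at 3 times are named by the gene at or nearest to their strongest window, that 10 genes are named whatever their value (taz1, clr4, mei4, ssm4, mcp7, rec8, tlh1, tlh2, ura4 and hus5), and that in series 2 the 5 highest and 5 lowest running means over 3 windows, 1 per 20 kb, are named. After the data were seen, naming was limited to protein-coding, rRNA and tRNA genes. Means are given with the SD over the 3 times.

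The 11 lists, also fixed before the data were examined, were the outer 100 kb of chromosomes 1 and 2, the outer 100 kb of chromosome 3, the centromeres, the mating-type region, 11 meiotic genes of the Mmi1 pathway (mcp5 under its annotated name num1), internal sites with at least 2 hexamers of the telomeric type within 30 bp, early peaks of the series 2 wt array, Tf2 elements, wtf genes, ribosomal protein genes and tRNA genes. Genes were taken with 2000 bp on each side and hexamer sites with 2.5 kb. Lists were tested with camera, the correlation between windows estimated. Origin peaks were maxima of the 3-window running mean of the 9 arrays, at least 0.5 log2 high and 10000 bp from the next, valued over probes within 2000 bp. For series 2, list medians were ranked among 10000 random lists of the same size matched on mean ratio. A simulation with 100 draws gave the link between the deletion contrasts that their shared wt arrays alone produce.

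The analysis was checked on simulated data. Of 100 windows given a difference of 1 log2 at the arrays' own noise, 90% were called in the taz1del contrast and 91% in the clr4del contrast, 40% and 37% at 0.5 log2, with 9 and 4 false calls. That noise was drawn independently for each window and with the same size on every array. The check therefore does not cover windows that vary together or arrays that differ in spread.

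Alternatives were normexp background correction with an offset of 50, equal median absolute deviation of the arrays (equal spread), quantile normalization between arrays, loess within arrays, the deposited value table, only probes well above background, windows of 1 or 5 kb, time left out or linear, slide as a further block, only the genotypes compared, windows of repeated sequence left out, each array left out in turn, camera with a preset correlation of 0.01, fry, the outer 50 kb, other hexamer definitions, and other peak thresholds. Normexp used median signals, since the files give no mean signals. The equal-spread and quantile settings for origins, and series 2 without the probes that lost their input signal, were chosen after seeing the data. Preparation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and Biopython 1.88, and figures matplotlib 3.10.9.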

Results

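DNA newly made in hydroxyurea, a drug that slows replication forks and holds back late origins, was mapped in fission yeast with the thymidine analogue BrdU. Cells with the cdc25-22 mutation were arrested before mitosis, released with both compounds, and collected at times labelled 80 to 140 min. BrdU-labelled DNA was pulled down and set against whole-cell extract DNA on the same 60-mer array, so that a higher log2 ratio means more BrdU at that place relative to the rest of the genome. The 11 arrays fall into 5 groups. In series 1, wild type (wt), cells without taz1 (taz1del) and cells without clr4 (clr4del) have 3 arrays each, 1 per time at 100, 120 and 140 min. In series 2, wt and a strain labelled telr delta Is3 have 1 array each at 80 min. Median signal over local background was 57.3 to 217 in the input channel and 46.1 to 1211 in the IP channel, and the number of arrays limits the precision. Positions are the array's own coordinates, for which the sources used here give no genome build.

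The taz1del and clr4del arrays carried the labelled deletions. In taz1del the median log2 input signal of the 7 probes in taz1 was -9.26 to -4.49 relative to the array median, depending on the array, and in clr4del that of the 5 probes in clr4 was -8.57 to -7.30. The telr delta Is3 array had an input signal over 3 log2 below the median of the other arrays at 27 neighbouring probes, positions 2932500 to 2940300 of chromosome 1. Whether this stretch is the change named in that label is not given in the sources used here. The spread of the log2 ratios (median absolute deviation) also differed between groups. It was 0.55, 0.43 and 0.33 in wt at 100, 120 and 140 min, 0.30, 0.26 and 0.27 in taz1del, and 0.45, 0.31 and 0.32 in clr4del.

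The first comparison asks which regions take up BrdU differently without Taz1, the protein that binds telomeric repeats. Without it, the outer 100 kb of chromosomes 1 and 2, the subtelomeres, went from depleted to near the genome's level. Their mean ratio was -1.30 in wt and 0.12 in taz1del, a difference of 1.42 ± 0.36 (SD over the 3 times, n = 3 arrays per genotype), and 172 of 193 windows rose, 184 when adjusted over the list alone. All 4 ends took part, with 1.44 ± 0.39 at the left end of chromosome 1 and 1.70 ± 0.38 at its right end, and 1.329 ± 0.356 and 1.204 ± 0.3001 at the left and right ends of chromosome 2. The difference went from 2.09 ± 0.45 within 25 kb of the end (44 of 44 windows rose) to 0.93 ± 0.32 at 50 to 100 kb (77 of 98 rose) and 0.33 ± 0.14 at 100 to 150 kb (25 of 99 rose). Further in it was larger again, 0.39 ± 0.11 at 150 to 200 kb (42 of 100 rose) and 0.56 ± 0.08 at 200 to 300 kb (119 of 200 rose), before 0.22 ± 0.04 at 300 to 400 kb (49 of 197 rose). The window at tlh1, a helicase-like gene next to the telomere, rose by 1.86 ± 0.08 (limma adjusted p = 3.05e-05), higher at 3 of 3 times. At the ends of chromosome 3, which hold ribosomal DNA, the mean was -0.03 ± 0.04 and the median -0.21. There 15 windows rose, 7 fell, and the mean became 0.01 with arrays scaled to equal spread.

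**Figure D1:**
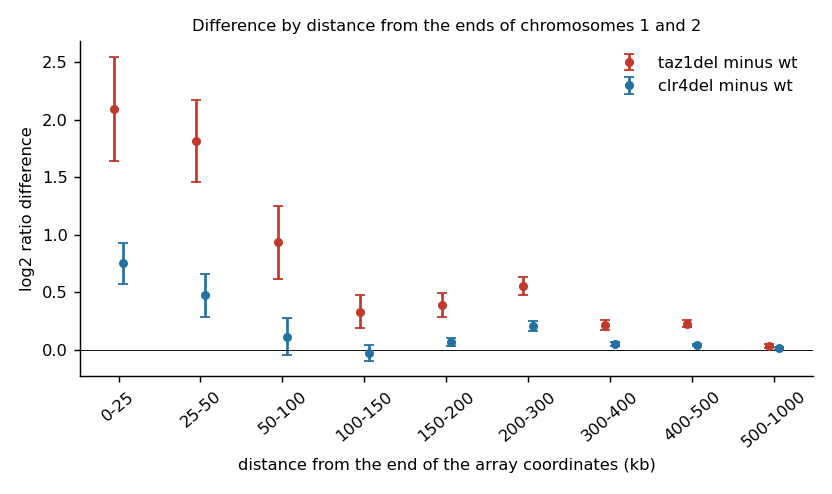
Mean difference in log2 ratio (vertical axis) of windows at a given distance in kb from the ends of chromosomes 1 and 2 (horizontal axis), for taz1del minus wt and clr4del minus wt; bars are the SD over the 3 times. The taz1del difference is 2.09 within 25 kb, 0.33 at 100 to 150 kb, 0.56 at 200 to 300 kb and 0.03 at 500 to 1000 kb, and the clr4del difference 0.75, -0.03, 0.21 and 0.01.

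The 12 largest higher domains in taz1del comprised 6 at these ends, 2 in ribosomal DNA and 4 inside the chromosome arms. At the ends, the domain near SPBC1348.15 (chromosome 2, 1 to 16000) rose by 2.12 ± 0.38, that near SPAC186.08C (chromosome 1, 5484001 to 5576000) by 1.85 ± 0.41, that near SPBC1348.08C by 1.64 ± 0.49 and that near tlh1 (chromosome 1, 1 to 102000) by 1.44 ± 0.39. The hexose transporter gene ght7 marked a domain up 1.32 ± 0.34 and SPBPB2B2.16C another up 1.28 ± 0.31. The ribosomal DNA domains near SPRRNA.42 (chromosome 3, 1 to 24000) and SPRRNA.49 (2440001 to 2450000) rose by 1.18 ± 0.04 and 1.12 ± 0.05. Inside the arms, the domain at pvg3, for a cell-wall galactose modification, rose by 0.98 ± 0.21 (chromosome 2, 2398001 to 2426000), that near mug157 by 0.85 ± 0.37 (chromosome 1, 4594001 to 4604000), that at mod21, for a gamma-tubulin complex protein, by 0.85 ± 0.17 (chromosome 1, 208001 to 316000) and that at gpa2, for the G protein of glucose sensing, by 0.84 ± 0.18 (chromosome 1, 2510001 to 2550000). These 4 had mean ratios of -1.09 to -0.65 in wt. With arrays scaled to equal spread, 11 of the 12 kept their call, and the domain near SPRRNA.49 did not, at 1.01 against 1.12.

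**Figure D2:**
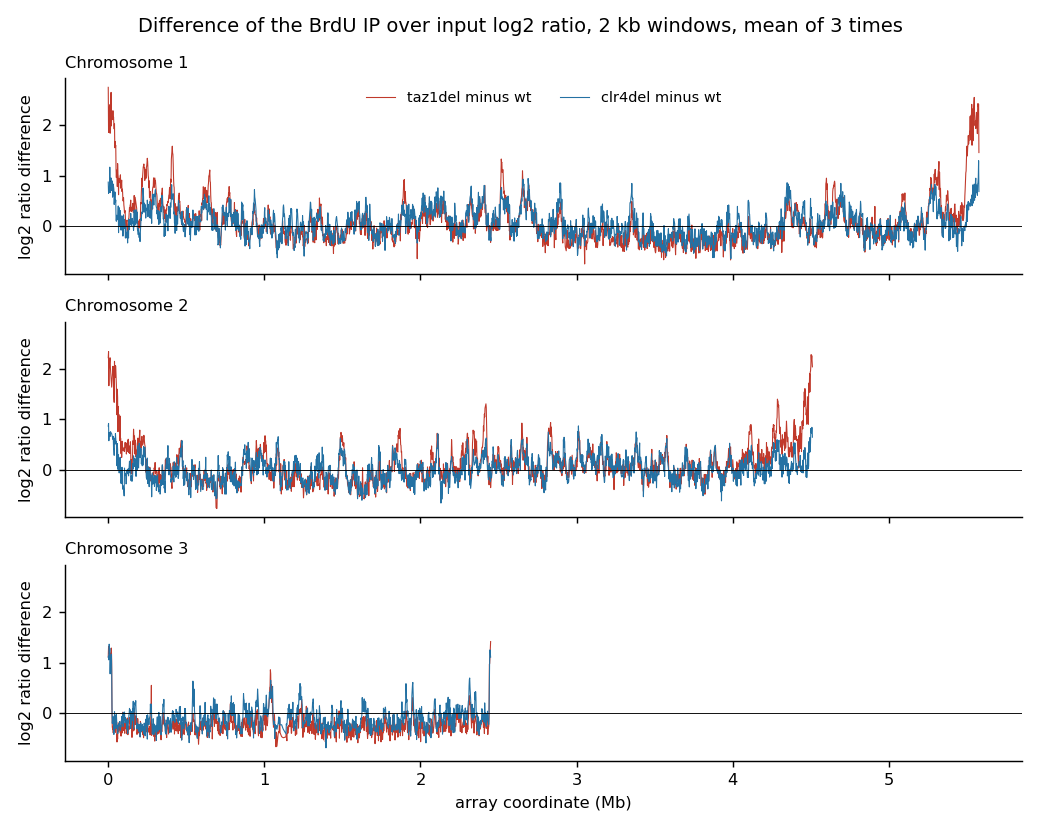
Difference in log2 ratio (vertical axis) in 2 kb windows along the array coordinates in Mb (horizontal axis) of chromosomes 1, 2 and 3, for taz1del minus wt and clr4del minus wt, each the mean of 3 times. The taz1del line is highest at the 4 ends of chromosomes 1 and 2, where 172 of 193 windows rose.

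Over the genome, 766 of 6207 windows rose and 244 fell in taz1del, 75.8% of the calls being higher. The 12 largest falls were 11 single windows and 1 pair, each above the array median in wt. They were at or near the aconitase gene aco1 (-0.74 ± 0.40), the flocculin gene pfl2 (-0.66 ± 0.43), cyk3 (-0.64 ± 0.24), SPATRNAALA.04 (-0.63 ± 0.30), the acetyl-CoA synthetase gene acs1 (-0.60 ± 0.31), SPBTRNATYR.03, rsc7, ntr2, SPBTRNAILE.07, SPCC285.05, hel2 and sly1 (-0.58 to -0.53). Scaling the arrays to equal spread gave 369 higher and 19 lower windows (95.1% higher), of which 361 and 10 were among the unscaled calls. Quantile normalization gave 369 and 26 (93.4%), of which 362 and 11 were among them. With equal spread only cyk3 and ntr2 of the 12 largest falls kept their call (-0.63 and -0.47). Without a call, aco1 had -0.54, SPCC285.05 -0.43, rsc7 -0.40, sly1 -0.38, acs1 -0.34, hel2 -0.33, SPBTRNAILE.07 -0.29, pfl2 -0.27, SPBTRNATYR.03 -0.14 and SPATRNAALA.04 -0.03. The counts also rest on single arrays: without wt replicate 1 they were 380 and 3, without wt replicate 2 449 and 20, without taz1del replicate 1 506 and 29, without taz1del replicate 2 479 and 34, without taz1del replicate 3 551 and 65, without clr4del replicate 1 639 and 102, without clr4del replicate 2 1015 and 693, and without wt replicate 3 774 and 379.

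The lists fixed for taz1del gave smaller values. Windows at the centromeres had a mean difference of -0.39 ± 0.09 and 20 of 54 fell, 26 when adjusted over the list alone. With arrays scaled to equal spread the centromere mean was -0.23 ± 0.26 (-0.05, -0.11 and -0.53 at the 3 times). By channel, their log2 input signal was 0.23 ± 0.04 higher and their IP signal 0.16 ± 0.13 lower, so that the input moved more than the IP signal. Windows at the wtf genes, a family of meiotic drivers, had -0.30 ± 0.08, and 11 of 78 fell, 32 over the list alone (-0.14 ± 0.09 with equal spread). Windows at early peaks had -0.27 ± 0.08 and 55 of 526 fell, 0 over the list alone by limma (210 below an unadjusted p of 0.05; -0.07 ± 0.07 with equal spread). At the meiotic genes silenced through Mmi1 the mean was -0.05 ± 0.04 with 0 of 45 windows called by limma (5 below an unadjusted p of 0.05, 4 of them lower). Internal sites with tandem telomere-like hexamers had -0.01 ± 0.04, 31 of 227 windows rising and 10 falling. The mating-type region had 0.06 ± 0.10 (3 of 16 rose), Tf2 retrotransposons -0.06 ± 0.07 (3 rose and 2 fell of 45; 0.01 with equal spread), ribosomal protein genes -0.08 ± 0.04 (22 rose and 16 fell of 396; -0.03 with equal spread) and tRNA genes -0.12 ± 0.02 (13 rose and 30 fell of 366; -0.08 ± 0.07 with equal spread). The lists are not separate, since 31 of the 54 centromere windows and 62 of the 526 windows at early peaks also belong to the tRNA list. Of the windows at genes named beforehand, those at clr4 (0.41 ± 0.26), mei4 (-0.16 ± 0.04), ssm4 (-0.19 ± 0.07), mcp7 (-0.02 ± 0.10), rec8 (0.06 ± 0.05), ura4 (-0.21 ± 0.24) and hus5 (-0.16 ± 0.14) were not called, tlh2 lies outside the windows, and the window at taz1 (-0.23 ± 0.42) covers the deleted stretch, so that its value says nothing about replication. At the 3 probes in ura4, the taz1del input was 0.41, 0.57 and 0.77 log2 above the other arrays at the 3 times. Their IP signal was 0.32, 0.35 and 0.29 above, so the lower ratio at ura4 cannot be read as less BrdU. With the correlation between windows estimated, camera called none of the 11 lists. The subtelomeres had an adjusted p = 0.149 at an estimated mean correlation of 0.577 between the windows of the list, and 0.0495 with equal spread, while the preset correlation gave 3.36e-80.

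**Figure D3:**
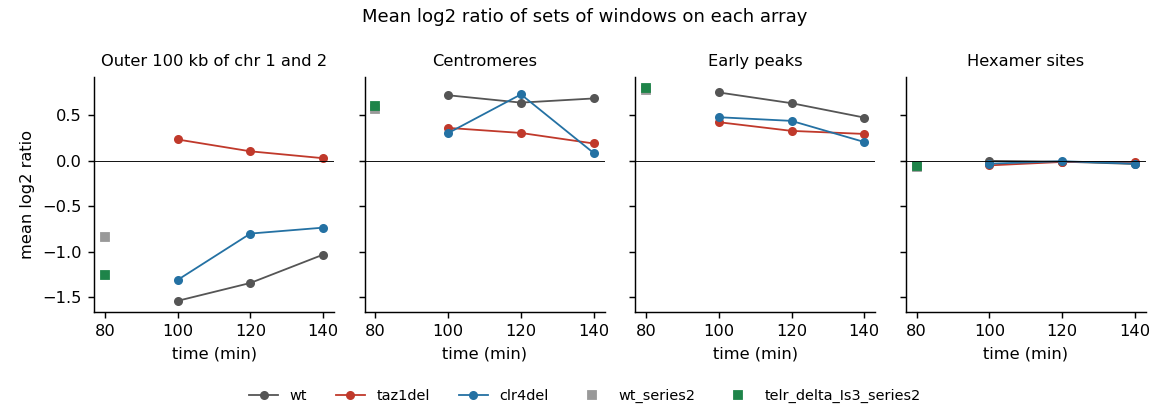
Mean log2 ratio (vertical axis) of 4 sets of windows on each of the 11 arrays against time in min (horizontal axis); circles joined by lines are series 1 and squares series 2. In the outer 100 kb of chromosomes 1 and 2 the wt mean of series 1 is -1.30, the clr4del mean -0.95 and the taz1del mean 0.12.

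At replication origins themselves the unscaled ratios moved the other way. The mean profile of the 9 arrays had 81 peaks, of which 76 were also at least 0.5 log2 high in wt of series 2 at 80 min. In taz1del 28 peaks fell and 0 rose (limma; 51 and 0 below an unadjusted p of 0.05), the mean ratio going from 0.92 to 0.56, a difference of -0.35 ± 0.15, negative at 81 of 81 peaks. Among them was the peak near SPCTRNALYS.10 at the centromere of chromosome 3 (-0.56, SE 0.13). Another was that at emc5, within the centromere windows of chromosome 1 (-0.47, SE 0.13). Both were picked after their values were seen. Over the centromere windows as a set, the log2 input signal was 0.23 ± 0.04 higher in taz1del and the IP signal 0.16 ± 0.13 lower. With arrays scaled to equal spread or quantile normalized, 0 peaks fell (2 and 3 below an unadjusted p of 0.05). The listed windows at early peaks went from -0.27 to -0.07 ± 0.07 with equal spread, so a narrower spread in taz1del may account for the fall. In clr4del 0 peaks rose and 0 fell (limma; 0 and 27 below an unadjusted p of 0.05), with a mean of -0.25 ± 0.01, negative at 77 of 81. With equal spread or quantile normalization limma again called 0 in clr4del, with 3 and 9 lower below an unadjusted p of 0.05.

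The clr4del comparison asks the same without Clr4, the enzyme that methylates histone H3 on lysine 9 in heterochromatin. The windows that rose most lay in ribosomal DNA and at the chromosome tips. The domain at SPRRNA.49 (chromosome 3, 2442001 to 2446000) rose by 1.19 ± 0.33 and that at SPRRNA.47 (chromosome 3, 1 to 24000) by 1.09 ± 0.45. At the tips the domain near SPAC750.08C rose by 0.86 ± 0.16, that at SPAC212.06C (chromosome 1, 1 to 28000) by 0.82 ± 0.11, that near SPBPB2B2.19C by 0.79 ± 0.23 and that near SPBC1348.15 by 0.74 ± 0.14, with those at SPAC186.04C, SPAC977.03, SPAC186.08C and pfl6 between 0.68 and 0.82. Inside the arms, the domain at sid2, for a septation kinase, rose by 0.73 ± 0.12 and that near ubc1, for a ubiquitin-conjugating enzyme, by 0.70 ± 0.07. Of the genes named beforehand, the tlh1 window rose by 0.65 ± 0.37 (limma adjusted p = 0.0471). Those at taz1 (-0.01 ± 0.27), mei4 (0.05 ± 0.21), ssm4 (-0.17 ± 0.14), mcp7 (0.00 ± 0.24), rec8 (0.09 ± 0.07), ura4 (-0.12 ± 0.10) and hus5 (-0.20 ± 0.20) were not called, and that at clr4 (0.14 ± 0.42) overlaps the deleted stretch. The subtelomeres of chromosomes 1 and 2 had a mean difference of 0.36 ± 0.16, with 28 of 193 windows up and 63 over the list alone. With equal spread that mean was 0.16 ± 0.20 (-0.06, 0.21 and 0.33 at the 3 times), and by channel the log2 input signal was 0.17 ± 0.16 lower and the IP signal 0.18 ± 0.07 higher.

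The 12 named falls in clr4del were single windows, at or near the desaturase gene ole1 (-0.69 ± 0.38), meu31 (-0.62 ± 0.42), coq12 (-0.62 ± 0.14), the plasma membrane proton pump gene pma1 (-0.62 ± 0.23), hrr1, eta2, mug42, ser3, usp102, per1, hnt3 and SPBTRNAARG.07 (-0.59 to -0.52). In all, 229 windows rose and 25 fell (90.2% higher). Centromeres gave -0.41, 0.09 and -0.60 at the 3 times, with 2 of 54 windows lower, 3 over the list alone (-0.24, 0.32 and -0.70 with equal spread). Early peaks had -0.24 ± 0.04 (9 of 526 fell, 0 over the list alone, 168 below an unadjusted p of 0.05, -0.15 ± 0.15 with equal spread), wtf genes -0.17 ± 0.04 (0 of 78 called by limma, 18 lower below an unadjusted p of 0.05, -0.08 ± 0.10 with equal spread), tRNA genes -0.13 ± 0.13 (9 rose and 5 fell of 366) and the mating-type region -0.11 ± 0.21 (2 rose and 2 fell of 16). Ribosomal protein genes had -0.05 ± 0.03 (5 rose, 1 fell), Mmi1 targets -0.02 ± 0.02 (1 rose), hexamer sites -0.01 ± 0.02 (9 rose, 1 fell) and Tf2 elements 0.01 ± 0.05 (1 rose). At the ends of chromosome 3 the mean was 0.05 ± 0.10, the median -0.12 and camera's direction down (9 windows rose), and without repeated sequence the mean was -0.14. Camera with estimated correlation called none of the 11 lists, the subtelomeres having an adjusted p = 0.512.

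These clr4del calls depended on the arrays used. Both counts were 0 without clr4del replicate 1 or replicate 3 (688 higher and 386 lower, then 729 and 359, below an unadjusted p of 0.05), and 498 and 394 without clr4del replicate 2. They were 5 and 0 without wt replicate 1, 2 and 0 without wt replicate 2, 146 and 10 without wt replicate 3, 339 and 45 without taz1del replicate 1, 37 and 0 without taz1del replicate 2 and 63 and 0 without taz1del replicate 3. The clr4del array at 120 min had r = 0.874 with wt at 140 min, against 0.704 and 0.549 with clr4del at 100 and 140 min. The clr4del array at 100 min had r = 0.925 with wt at 100 min and 0.832 with clr4del at 140 min. With equal spread 0 windows were called by limma (370 higher and 204 lower below an unadjusted p of 0.05), as with quantile normalization (362 and 253) and with slide as a block (443 and 177), clr4del at 120 and 140 min having had a slide of its own. None of the 24 named domains and windows kept its call with equal spread, with differences of 1.12 against 1.19 at SPRRNA.49, 1.01 against 1.09 at SPRRNA.47, -0.49 against -0.53 at usp102 and 0.38 against 0.71 at SPAC186.08C. Between arrays of 1 slide, at 100 min, the subtelomere difference was 0.23. The tlh1 call ended without any of clr4del replicates 1 and 3 (0.76 and 0.42), wt replicates 1, 2 and 3 (0.69, 0.70 and 0.57) or taz1del replicates 2 and 3 (0.65 both).

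The deletions were then compared with each other, a test of whether their effects differ that uses no wt array in the difference. Windows of the subtelomeres were higher in taz1del than in clr4del, by 1.068 ± 0.415, with 155 of 193 windows called and 187 over the list alone. As a list, camera with estimated correlation did not call them (adjusted p = 0.209). Camera with the preset correlation (adjusted p = 2.46e-115) and fry (adjusted p = 0.0386) did. The largest domains, at the 4 ends, were near SPBC1348.04 (1.37 ± 0.51), SPAC186.07C (1.33 ± 0.50), tlh1 (1.18 ± 0.43) and SPBPB2B2.14C (1.18 ± 0.43), followed by SPBC1348.12 (1.04 ± 0.45), SPBC1348.08C (0.92 ± 0.62), isp5 (0.85 ± 0.19), SPBPB10D8.04C, SPAPJ695.02, mug95, SPBC1921.04C and get1 (0.69 to 0.76). The domain at SPBC1921.04C (chromosome 2, 2402001 to 2424000) lies within that named for pvg3. Lower in taz1del were windows at or near tcb1 (-0.65 ± 0.28), cbp4 (-0.64 ± 0.07), pmd1 (-0.63 ± 0.31), sfk1 (-0.61 ± 0.16), alp14, put1, syo2, bud6, rpl1101, SPCC965.13, msw1 and dpp2 (-0.56 to -0.51). All 24 kept their call with arrays scaled to equal spread. Of the genes named beforehand, the tlh1 window was 1.21 ± 0.45 higher (limma adjusted p = 0.00123). Those at mei4 (-0.21 ± 0.17), ssm4 (-0.02 ± 0.07), mcp7 (-0.03 ± 0.17), rec8 (-0.03 ± 0.05), ura4 (-0.10 ± 0.14) and hus5 (0.04 ± 0.20) were not called, and those at taz1 (-0.21 ± 0.20) and clr4 (0.27 ± 0.26) overlap the deleted stretches. The raised input at ura4 in taz1del bears on the ura4 value here too.

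Between the deletions 270 windows were higher and 23 lower in taz1del (92.2% higher), 306 and 80 with equal spread (79.3%) and 325 and 154 after quantile normalization (67.8%). The counts were 93 and 0 without clr4del replicate 1, 485 and 208 without clr4del replicate 2, 183 and 1 without clr4del replicate 3, 140 and 0 without taz1del replicate 1, 149 and 6 without taz1del replicate 2, 232 and 4 without taz1del replicate 3, 212 and 4 without wt replicate 1 and 238 and 9 without wt replicate 2. Against wt, the deletions shared 158 higher windows and 16 lower ones, where independent lists would share 28.3 and 0.983. With equal spread or quantile normalization none were shared, since limma called 0 windows in clr4del (370 and 362 higher, 204 and 253 lower below an unadjusted p of 0.05). Their differences from wt had a covariance of 0.0834 over windows, 0.0104 in simulations in which only the shared wt arrays linked them, a Pearson r of 0.719 (0.499 simulated) and 78.2% of windows with the same sign (66.7% simulated). Windows are not independent replicates, and the 3 wt arrays could not be split between the deletions. Part of the excess over independent lists can therefore come from sharing the wt arrays. The spread of the wt arrays, the widest of the 3 genotypes at each time, can add to that excess and to the excess over the simulations.

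Between 100 and 140 min, over the 3 genotypes, 368 windows rose and 88 fell. Late regions inside the arms, defined as the lowest 10% of the series 2 wt array, gained 0.48 ± 0.05 (SD over the 3 genotypes), and 249 of 592 windows rose. Early peaks changed by -0.23 ± 0.08, and 23 of 526 windows fell. The spread of the ratios also narrowed from 100 to 140 min, and how much of either change it gives was not tested. The largest gains were near ubc1 (1.25 ± 0.13), sea2 (1.205 ± 0.164) and msa1 (1.19 ± 0.45), and the largest falls near SPBPJ4664.02 (-1.204 ± 0.921), gdh1 (-0.81 ± 0.38) and pfl3 (-0.78 ± 0.32), all 6 picked after their values were seen. Subtelomeres differed by 0.51 in wt, 0.57 in clr4del and -0.21 in taz1del, and 2 of 193 windows rose. The total of 456 was 51 without wt replicate 1, 288 without wt replicate 2, 156 without wt replicate 3, 291 without taz1del replicate 2, 117 without taz1del replicate 3, 62 without clr4del replicate 1, 968 without clr4del replicate 2 and 195 without clr4del replicate 3. It was 0 with equal spread (limma; 698 below an unadjusted p of 0.05).

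In series 2 the strain labelled telr delta Is3 was set against wt at 80 min, 1 array each, so no error or test can be given. The arrays lay on different slides. IP signal over background was 46.1 in wt and 177 in telr delta Is3, and 897 and 39 probes were flagged as outliers. Strain can therefore not be told apart from slide or array signal. Over 6223 windows the arrays had r = 0.954. The largest difference, 1.72 higher, was a stretch of 6 kb near gpa2 (chromosome 1, 2516001 to 2522000), where the ratio was -1.79 in wt and -0.08 in telr delta Is3. It ranked 1 of 6217 running means, the next place being 0.75, near pyp2, followed by nvj2 (0.59), nuc1 (0.43) and lkh1 (0.39). The same 6 kb differed by 1.29 ± 0.47 in taz1del and by 0.68 ± 0.21 in clr4del in series 1. On the other side, subtelomeres of chromosomes 1 and 2 had a median difference of -0.43, and -0.28 with equal spread. The lowest domains were near grt1 (-0.94), cbm1 (-0.88), yhb1 (-0.86), SPAC212.03 and SPAPJ695.01C (-0.78 both), that near cbm1 lying in the stretch that lost input signal. In all, 16 running means were more than 0.5 higher and 83 more than 0.5 lower, and 72 of these 99 lay in the subtelomeres. That total was 30 with equal spread, 245 with normexp and 280 with windows of 1 kb. Early peaks, which were picked on this wt array, had a median difference of 0.03, and -0.01 with equal spread. The medians of the other 9 lists lay between -0.01 and 0.08. Among 10000 random lists matched on mean ratio, the subtelomeres ranked lowest and the other 9 lists stood at percentiles 19.1 to 93.1. The early peaks also ranked lowest, but picking them for high values on the wt array pushes their difference down, so that their rank tests nothing. The ranks only describe the 2 arrays, because adjoining windows vary together.

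**Figure D4:**
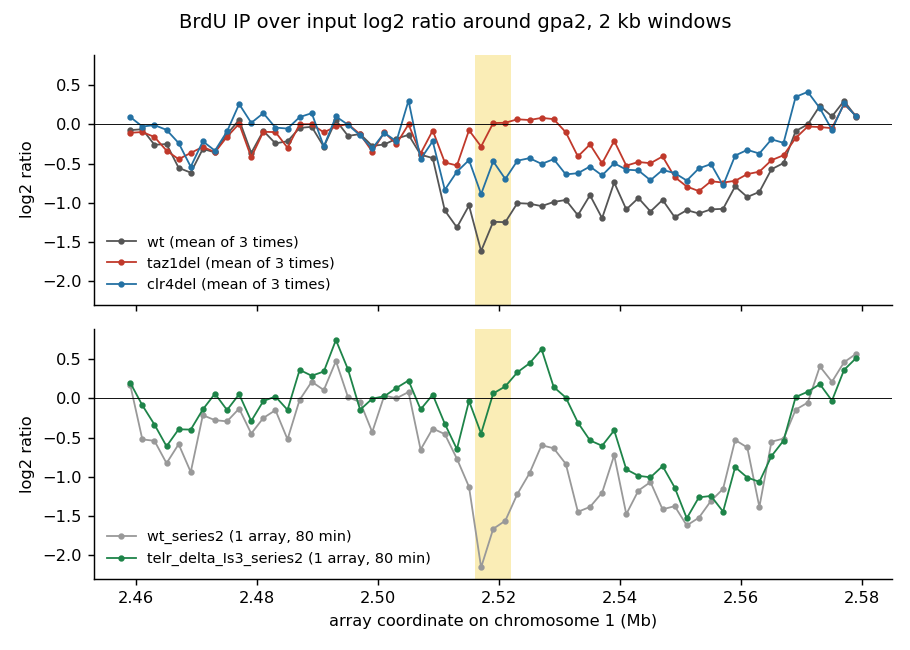
Log2 ratio (vertical axis) in 2 kb windows around gpa2, array coordinate of chromosome 1 in Mb (horizontal axis), for the 3 genotypes of series 1 (upper, means of 3 times) and the 2 arrays of series 2 (lower); the band marks 2516001 to 2522000. In the band, telr delta Is3 lies 1.72 above wt of its series, and taz1del 1.29 above wt of series 1.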

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

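The tests of spread, input signal and slide for the subtelomeres were chosen only after their rise was seen, and the counts over other splits were planned.

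A test of the difference itself picked out 293 windows at which taz1del and clr4del differ, 155 of them among the higher windows of the subtelomeres of chromosomes 1 and 2. Over all windows, the 6 arrays make 10 splits into 3 and 3, which cannot give a share under 0.05. The real split called 1010 windows between taz1del and wt, 254 between clr4del and wt, 293 between the deletions and 456 between 100 and 140 min, and the highest of the other splits called 0 in each case, so that 1 of 10 splits reached each real count. For origin peaks the real split called 28 between taz1del and wt against at most 1 in another split (1 of 10), and 0 between clr4del and wt against at most 6, a count that all 10 splits reach by construction and that tests nothing.

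The rise of the subtelomeres in taz1del (1.42 ± 0.36, n = 3 arrays per genotype) has 3 technical explanations that the tables argue against as its whole cause. A narrower spread of log2 ratios in taz1del would bring depleted regions nearer to 0, but the difference was still 1.31 (SD 0.06) with arrays scaled to equal spread. A loss of input signal would need a large fall, but the log2 input difference was -0.15 (SD 0.14). By design wt and taz1del shared a slide at each time, so slide does not separate them. The value of 1.06 at 140 min is the smallest of the 3 differences behind the mean, not a separate test. Leaving out repeated sequence, including the outer 30 kb, left a difference of 1.17. As a hypothesis found and tested on the same arrays, loss of Taz1 may let these regions copy DNA in hydroxyurea, while a different progress of the cultures through the cycle, for which the sources used here give no measure, stays open.

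Signal also appeared in 129 probes named pNSU, which belong to no comparison: their median log2 ratio in taz1del was 1.66 on average (1.85, 1.53 and 1.62 at 100, 120 and 140 min), against -2.45, -1.06 and -0.72 in wt and -1.78, 0.00 and -0.06 in clr4del, and their median log2 input signal was 1.61, 0.96 and 0.88 in taz1del against 2.749, 2.154 and 2.111 in wt.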

How the results depend on the processing

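Of the alternatives, those for origins with equal spread or quantile normalization and series 2 without probes that lost their input signal were chosen only after the result was seen. No result changed direction past its threshold, the filter on dim probes moved none, the deposited value table equals the signals used and so tests nothing, and the subtelomere difference in taz1del stayed between 1.13 and 1.90 under the planned normalizations. The cause of the shifts that follow was not tested, except where fewer arrays are the cause by construction. Counts are of windows higher and lower unless stated. With normexp, clr4del against wt had 56 lower (Mmi1 targets 0.00392), the deletions 55 lower, time 793 and series 2 245 running means. With equal spread, taz1del against wt had 369 and 19 (subtelomeres 1.31, adjusted p = 0.0495 against 0.0495 to 0.314 over its alternatives with camera's estimated correlation, chromosome 3 ends 0.00924, Tf2 0.00980), clr4del 0 and 0, the deletions 80 lower, time 0, origins 0 lower in taz1del and series 2 30. With quantile normalization these were 369 and 26, 0 and 0, 154 lower, 0 and 0 lower. With loess, taz1del had 403 and 63 (chromosome 3 ends 0.0710), clr4del 40 and 0, the deletions 10 lower and time 105. Windows of 1 kb gave 98 lower in taz1del, 1 and 0 in clr4del, 11 lower between the deletions, time 225 and series 2 280. Windows of 5 kb, with fewer tested, gave 501 and 487, 182 lower in clr4del and 53 lower between the deletions. Time left out gave 450 and 25, 0 and 0, and 9 lower; linear time gave 59 lower in clr4del and 35 lower between the deletions. Slide as a block gave 102 lower in taz1del, 0 and 0 in clr4del (Mmi1 targets 0.0224), 114 and 0 between the deletions and time 0. Only the genotypes compared gave 100 and 0 in clr4del and 8 lower between the deletions. Without repeated sequence the chromosome 3 ends in clr4del were at -0.14. Where limma called 0, between 362 and 729 windows were higher and 177 to 849 lower in clr4del below an unadjusted p of 0.05, 180 to 314 lower between the deletions, 698 to 773 changed with time, and 2 to 3 origins lower in taz1del. Camera with the preset correlation of 0.01 passed the threshold for taz1del at subtelomeres (1.42), chromosome 3 ends (-0.0309), centromeres (-0.39), early peaks (-0.27), wtf (-0.30), ribosomal protein (-0.0803) and tRNA genes (-0.12), and for clr4del at subtelomeres (0.36), centromeres (-0.31), early peaks (-0.24), wtf (-0.17), ribosomal protein (-0.0545) and tRNA genes (-0.13). None of these held with the estimated correlation in the main setting. Fry, which asks only whether a list's windows move 1 way, passed it for subtelomeres (1.42), early peaks (-0.27) and wtf genes (-0.30) in taz1del and for early peaks (-0.24) and wtf genes (-0.17) in clr4del. Origins lower in taz1del were 47 of 208 with a peak threshold of 0.25, 2 of 3 with 1, and 61 of 178 on series 2 wt peaks, where 6 fell in clr4del. Leaving out 1 array gave 380 to 1015 higher and 3 to 693 lower in taz1del, 0 to 498 and 0 to 394 in clr4del, 93 to 485 and 0 to 208 between the deletions, and 51 to 968 with time. Early peaks then had -0.32 to -0.24 in taz1del and -0.28 to -0.21 in clr4del, both past the threshold without taz1del replicate 3 (-0.32 and -0.24). Of the named domains under all settings, 1063 values stayed past the threshold and 503 did not. Of the fixed genes, 547 stayed as they were, 20 moved, 13 lost and 8 gained a call. Series 2 list medians and counts moved in 19 cases, and 96 running means were left without probes that lost their input. The lowest IP signal over background was 46.1, in series 2 wt.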

Other observations

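Chosen only after the results were seen were the tests of the early peaks, of the internal windows called higher and of the stretch near gpa2, while those of late internal windows were written before.

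Windows of the ribosomal RNA genes on chromosome 3 went from -0.58 in wt to 0.06 in taz1del and 0.01 in clr4del. The differences were 0.64 ± 0.05 (13 of 21 windows rose) and 0.59 ± 0.31 (9 of 21 rose). Between the deletions the mean was 0.05 ± 0.35, smaller than its spread. From 100 to 140 min these windows gained 0.55 ± 0.03 over the 3 genotypes, and 10 of 21 rose. The 61 mitochondrial probes had median ratios of 1.29, 0.80 and 0.69 in wt, 1.138, 0.820 and 0.404 in taz1del and 0.41, 0.82 and 0.01 in clr4del at 100, 120 and 140 min. The 110 probes of the mating-type cassettes had 0.18, 0.20 and 0.34 in wt, 0.21, 0.19 and 0.22 in taz1del and 0.09, 0.04 and 0.06 in clr4del.

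In taz1del early peaks were lower (-0.27 ± 0.08) and late regions inside the arms higher (0.47 ± 0.05), and early peaks were lower in clr4del too (-0.24 ± 0.04). With arrays scaled to equal spread these values were -0.0664 (SD 0.0733), 0.16 (SD 0.24) and -0.15 (SD 0.15), so that a narrower spread of log2 ratios may account for the first and the second, and in clr4del spread and a fall of early peaks cannot be told apart because the value lies about 1 SD from 0. A fall of the input signal in late regions is argued against by its difference of -0.0726. The 580 windows over 100 kb from an end that rose in taz1del went from 0.67 ± 0.11 to 0.49 ± 0.14 with equal spread and 198 stayed called. As many windows picked at 2 times and valued at the third went from 0.61 ± 0.13 to 0.42 ± 0.12. Valued at 100, 120 and 140 min they had 0.71, 0.64 and 0.46, and 0.27, 0.46 and 0.51 with equal spread. These values stayed above 0, but spread may account for much of the rise at 100 min. Whether it is the whole cause cannot be told from windows picked on these same arrays. Whether a narrower spread comes from the labelling, from the pull-down or from replication itself stays open.

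The stretch near gpa2 rose in taz1del and was the place that differed most in telr delta Is3. There the difference between the 2 arrays of series 2 was 1.72 (SE 0.09 over 20 probes), and 1.37 (SE 0.07) with equal spread, while the input signal was 0.32 (SE 0.07) higher. On these 2 arrays neither spread nor a loss of input DNA gives the whole difference. The SEs cover neighbouring probes, not cultures, at a place picked for its rank, and are no test. With equal spread the same stretch differed by 1.06 ± 0.10 in taz1del and by 0.48 ± 0.15 in clr4del. Whether the strains share a cause there was not tested. With 1 array per strain, each on its own slide, a difference between cultures, slides or arrays stays open. The sources used here do not say where Is3 lies.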
